A study of Mus musculus with 6 samples.

How the data were processed

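Messenger RNA from the cortex of 5XFAD mice was profiled by sequencing in 6 libraries. Groups were taken from the sample titles and the treatment label: 3 libraries were labelled as controls and 3 as cell-treated. The design text uses the words control and experimental the other way round, so the titles and the treatment label, not those words, decided which libraries were cell-treated. The count table names the columns of one group for the disease, a name that the titles do not use. They were taken as the controls by inference, since the remaining columns carry the word treated and all mice are 5XFAD, and the sign of every difference depends on this. The design text gives 3 biological replicates per group, so the p-values of single genes measure the spread among these samples. Whether control mice received a sham injection is not given in the sources used here. All libraries carried the same batch label. Per the labels' protocols, polyadenylated RNA was selected, primed with random hexamers and amplified by PCR; a strand-marking kit is not named. Overlapping and antisense genes can therefore share reads.

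The deposited count table held whole-number counts of reads for 54532 gene identifiers in each of the 6 libraries. The submitters' processing notes name HISAT2 2.0.5, featureCounts and DESeq2, with no order or settings. The genome build is not given in the sources used here. Of 54409 identifiers shared with the GENCODE M21 annotation of GRCm38, 98.3% had the same start and end, and coordinates are given as deposited. The deposited FPKM table equalled the counts divided by gene length and by a per-library total. That total was the sum of counts multiplied by a factor between 0.953 and 1.03, so the FPKM values carry a library scaling chosen by the authors. A further deposited table of group FPKM repeated the same columns with their means and was not used. Human reads from grafted cells or from the transgenes were not separated from mouse reads, so mouse App counts can include transgene reads.

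Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15), scaled with TMM factors and tested with the robust quasi-likelihood F test of cell-treated against control libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors of log2 fold changes were derived from the F statistic. CPM values are TMM-scaled, and n is 3 libraries per group unless given otherwise. Total counts ranged from 14221519 to 16696463 per library.

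Before the data were examined, 30 gene lists were fixed. The sex-linked list was used only to look at the sex of the mice. The other 29 lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 29 lists. Camera compares the genes of a list with the other genes. At this preset its p-values are too small where the genes of a list move together across libraries. Estimated correlations within the called lists ran from 0.231 to 0.839. The score of a list in a library is the mean over its genes of log2 CPM minus the mean of the 6 libraries. Within each list, edgeR p-values were also adjusted over the list alone. Genes were named by a rule fixed at the same time. It takes genes past the threshold and, where fewer than 5 passed in a direction, the 10 of smallest p with an average log2 CPM of at least 1, no predicted-gene symbol and no overlap between the groups. It adds the leading members of each list and App, Thy1, Mapt, Gad1, Gad2, Pvalb, Sst, Gfap, Trem2 and Cst7. Other genes are named as members of a list, as genes that DESeq2 called, or as genes chosen after their values were seen, where this is stated. Some genes that the rule takes are not reported here.

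The alternatives fixed beforehand were DESeq2 1.42.0, limma voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1), other scaling factors, other filters, protein-coding genes alone, the replicate number as a block, each library left out, camera with an estimated correlation, and fry. With libraries left out, lists were tested by camera with its preset correlation alone. In DESeq2, 52 genes were set aside as count outliers and have no p-value. The gene test and the list test were tested on simulated data drawn from the means, the library sizes and edgeR's trended dispersions of the real samples, with 200 genes changed among 16701 tested. Of genes changed 1.5-fold, 1.49% were called, of those changed 2-fold 26.9%, and of those changed 4-fold 84.8%, with 0 false calls. Real libraries can differ by more than the trend, so these shares do not carry over to the real genes. A list of 12 genes shifted by -0.5 on the log2 scale was recovered by camera at an adjusted p of 0.00412. The genes were simulated independently of each other, so this does not carry over to lists whose genes move together. Figures were drawn with matplotlib 3.10.9.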

Results

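Cortical gene expression was measured in 5XFAD mice, a model that carries human transgenes with familial Alzheimer's disease mutations under Thy1 promoter elements and deposits amyloid in the brain. The 3 control libraries came from mice without cell therapy and the 3 cell-treated libraries from mice that had received it. The series title describes the therapy as human GABAergic interneurons, a class of inhibitory neurons, made from induced pluripotent stem cells. Total counts were 14576319, 14221519 and 15607280 in control libraries 1, 2 and 3, and 15455745, 14880969 and 16696463 in cell-treated libraries 1, 2 and 3. Cell-treated library 3 stood apart from the other 5: its mean Pearson correlation with them across genes, which are not independent replicates, was 0.936, against 0.963 to 0.969 for the others. It held 253 genes at 10 CPM or more that lay at least 2-fold above the next library, whereas the other libraries held between 4 and 59 such genes. Mitochondrially encoded genes took 1.95% of the counts in control library 3 and between 4.49% and 8.78% in the other 5.

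The comparison of the groups addressed whether cortical gene expression in the model differed between mice with and without the transplanted interneurons. Genes of striatal projection neurons had lower levels in the cell-treated libraries, led by Ppp1r1b, a dopamine-regulated phosphatase inhibitor, at 92.6 ± 31.1 CPM against 314 ± 143.5 in controls (SD, n = 3 each). Control library 3 held the highest levels of these genes, and without it the median log2 fold change of the list was -0.66 instead of -1.50. Hemoglobin genes had higher levels, with Hba-a1 at 66.7 ± 43.0 CPM against 8.60 ± 7.25 (SD, n = 3 each). The striatum list and the blood list that holds these genes passed camera with its preset correlation and not with an estimated one (adjusted p 0.812 each). The lists of GABAergic interneurons, of amyloid and tau metabolism and of disease-associated microglia did not pass their test. No single gene passed the test: of 17042 genes tested with edgeR's quasi-likelihood test, 0 were higher and 0 lower at an adjusted p of 0.05, and the smallest adjusted p was 0.999. At an unadjusted p under 0.05 there were 340 genes, 160 higher and 180 lower, against 852 expected by chance. With single libraries left out the count ran from 203 (control library 2) to 796 (cell-treated library 3). It was 1531 without control library 3 and cell-treated library 3, and 1887 by limma voom with sample quality weights. Both of these settings were chosen after seeing the data. The low count thus depended on the libraries used, and it does not show that the groups are alike. DESeq2 called 9 genes, limma voom 0, and edgeR without a low-count filter 1, Tmem254c, at an adjusted p of 0.0287. The groups did not overlap for 1465 genes, 8.60% of those tested, where chance gives 10%.

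Among genes that met the naming rule above, the 10 of smallest p with higher values in cell-treated libraries, none of which passed in edgeR, were Tmem254c, Hbb-bt, Slc8a1, Mid1, Hba-a1, Gpr21, Palm2, Ipcef1, Hba-a2 and Hbb-bs. G530011O06Rik, at an unadjusted p of 0.000186 in edgeR, was left out by the rule for its average log2 CPM of 0.86. Tmem254c (ENSMUSG00000072680, chromosome 14, 26063919 to 26067355) had the largest log2 fold change of these 10, 3.69 ± 0.494 (SE). It was at 3.56 ± 0.895 CPM against 0.267 ± 0.122 (SD, n = 3 each). It has near-identical copies in the mouse genome, so the assignment of its reads is uncertain. Slc8a1, a sodium-calcium exchanger (ENSMUSG00000054640, chromosome 17, 81388691 to 81649607), was at 22.3 ± 3.10 CPM against 10.7 ± 1.10 (SD, n = 3 each), a log2 fold change of 1.07 ± 0.206 (SE). Mid1, a ubiquitin ligase of microtubules (X, 169685199 to 170005736), had a log2 fold change of 1.64 ± 0.385 (SE), and it overlaps G530011O06Rik (X, 169975043 to 169978917), which DESeq2 called at an adjusted p of 0.0170. The other values were 1.26 for Gpr21, 0.98 for Palm2 and 0.71 for Ipcef1 on the log2 scale. DESeq2 called 5 genes as higher: Tmem254c, at an adjusted p of 0.00013, G530011O06Rik, Hbb-bt, Hba-a1 and Hba-a2.

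Among genes that met the naming rule, the 10 of smallest p with lower values were Ppp1r1b, Lrrc10b, Ptprv, Adora2a, Rgs9, Sh3rf2, Cd74, Rxrg, Snx22 and Slc26a10, and none of them passed in edgeR. Ppp1r1b (ENSMUSG00000061718, chromosome 11, 98348404 to 98357796) had a log2 fold change of -1.76 ± 0.388 (SE), and Adora2a, a striatal adenosine receptor (ENSMUSG00000020178, chromosome 10, 75316877 to 75334784), -2.59 ± 0.626 (SE). DESeq2 called 4 genes as lower, with adjusted p-values of 0.0195 for Ppp1r1b, 0.00999 for Lrrc10b, 0.0210 for Ptprv and 0.00924 for Adora2a. Without control library 3 the log2 fold changes were -1.37 for Ppp1r1b, -1.62 for Lrrc10b, -1.64 for Ptprv and -1.61 for Adora2a, and -1.07 instead of -1.80 for Rgs9. Snx22, a sorting nexin, was at 4.67 ± 0.347 CPM against 8.89 ± 0.942 (SD, n = 3 each). The remaining log2 fold changes were -2.30 for Sh3rf2, -1.22 for Cd74, -1.50 for Rxrg and -1.40 for Slc26a10.

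The transplanted cells were human GABAergic interneurons, whereas the counts are of mouse genes. Of 35 GABAergic interneuron genes, 21 had higher and 14 lower values in cell-treated libraries, and camera gave an adjusted p of 0.564. Their median log2 fold change was 0.080. With single libraries left out it ranged from -0.073 (cell-treated library 1) to 0.30 (control library 3, adjusted p 0.0988). None of the 35 passed edgeR's test over all genes or adjusted over the list alone. The list shares Tac1 with the further striatal genes below, at 117 CPM in control library 3 and at most 24.3 elsewhere. Control library 3 also held the highest levels of the striatal genes, so a difference in tissue between the pieces may act on this list. This was not tested. Gad1, which makes GABA from glutamate, was at 599 ± 337 CPM in cell-treated and 354.5 ± 175.5 in control libraries (SD, n = 3 each), and its highest value, 954 CPM, was in cell-treated library 1. Without that library its log2 fold change was 0.25 instead of 0.76, and it was 0.47 without control library 2 and 1.21 without control library 3. Cell-treated library 1 also held the highest levels of 8 of 9 olfactory bulb genes, with Trh as the exception, a list chosen after these values were seen: Cdhr1 reached 127 CPM there and at most 15.5 elsewhere, and Sp8 60.5 CPM and at most 3.90. Log2 fold changes were 0.35 ± 0.431 for Gad2, -0.39 ± 0.528 for Pvalb and -0.30 ± 0.454 for Sst (SE). With single libraries left out they ranged from -0.092 (without cell-treated library 3) to 0.72 (control library 3) for Gad2, from -0.93 (cell-treated library 2) to -0.071 (cell-treated library 1) for Pvalb and from -0.88 (cell-treated library 3) to 0.17 (control library 3) for Sst. Npy reached 505 CPM in cell-treated library 3 and between 28.7 and 80.6 in the other 5. Of 19 GABA receptor and inhibitory synapse genes, 13 had higher values, among them Gabra5 (log2 fold change 0.77 ± 0.271, SE, and 0.45 without cell-treated library 1), which lay above every control in all 3 cell-treated libraries. None passed over all genes or adjusted over the list alone, and the list had an adjusted p of 0.238, which was 0.00722 without cell-treated library 3 and 0.0371 without control library 3. Its median of 0.125 was -0.011 without cell-treated library 2 and 0.026 without cell-treated library 1. The list p-values with a library left out used camera's preset correlation. With an estimated one, run on all 6 libraries only, this list and the interneuron list each had an adjusted p of 0.812.

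**Figure D1:**
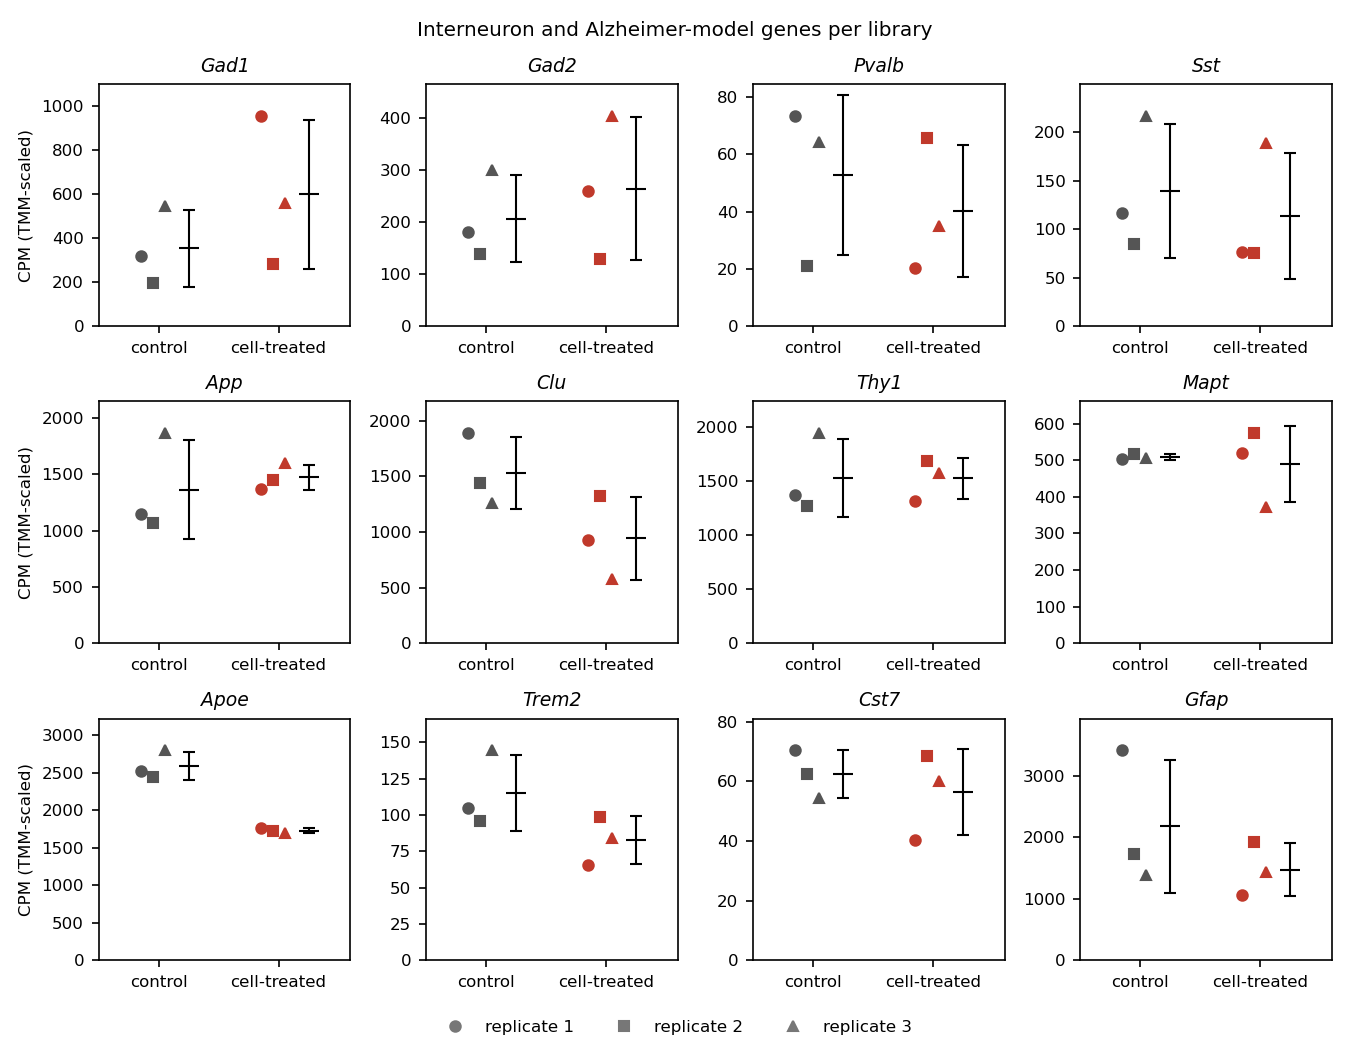
TMM-scaled CPM (linear axis from 0) of 12 genes in each library, with symbols for the replicate number and bars for the group mean ± SD (n = 3). Apoe lay between 1698 and 1761 CPM in cell-treated and between 2441 and 2802 CPM in control libraries, whereas the groups overlapped for the other 11 genes.

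Mouse App, which encodes the amyloid precursor protein, Thy1 and Mapt differed by less than their standard errors. App had a log2 fold change of 0.11 ± 0.265, Thy1 -0.0017 ± 0.244 and Mapt, which encodes tau, -0.056 ± 0.209 (SE). App was at 1866 CPM in control library 3 and between 1072 and 1596 in the other 5, and its log2 fold change without that library was 0.41. Of 22 genes of amyloid precursor processing and clearance, 10 had higher and 12 lower values (adjusted p 0.716 by camera), with Clu at -0.70 ± 0.328 (log2 fold change, SE), or -0.44 without cell-treated library 3. Of 28 genes of tau, its kinases and its phosphatases, 16 had higher and 12 lower values (adjusted p 0.267, median 0.076). The adjusted p was 0.0269 without control library 3, by camera with its preset correlation, and the median was -0.076 without cell-treated library 3. With an estimated correlation, run on all 6 libraries only, both lists had an adjusted p of 0.812. None of these genes passed over all genes or adjusted over the list alone.

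Disease-associated microglia, the activated state around plaques, gave 14 genes with higher and 15 with lower values, at a median log2 fold change of -0.057 and an adjusted p of 0.163 by camera. Apoe, a lipid carrier of glia, had the smallest p, at 1727 ± 31.6 CPM against 2590 ± 189 (SD, n = 3 each), a log2 fold change of -0.58 ± 0.202 (SE). Trem2, a lipid-sensing receptor of microglia, had a log2 fold change of -0.47 ± 0.226, or -0.28 without control library 3, and Cst7 -0.15 ± 0.225 (SE), which ranged with single libraries left out from -0.31 (cell-treated library 2) to 0.042 (cell-treated library 1). Spp1 reached 573 CPM and Lgals3 45.3 CPM in cell-treated library 3, against at most 106 and 4.28 elsewhere. Without cell-treated library 3 the list had a median of -0.29 and an adjusted p of 0.00011, and without cell-treated library 1 a median of 0.089 with no call. Complement and antigen presentation genes had an adjusted p of 0.163, with 11 values higher and 8 lower and a median of 0.157. Its leading members were of MHC class II: Cd74 was at 30.1 ± 8.17 CPM against 70.3 ± 26.5 (SD, n = 3 each), and H2-Ab1 and H2-Aa had log2 fold changes of -1.30 and -1.35. Without cell-treated library 3 this list had a median of -0.44 and an adjusted p of 4.81e-06, and without cell-treated library 1 a median of 0.465 and an adjusted p of 0.446. The p-values with a library left out are from camera with its preset correlation. With an estimated one, run on all 6 libraries only, this list and disease-associated microglia each had an adjusted p of 0.812. Homeostatic microglia (adjusted p 0.678) and cytokines and inflammasome (0.581) were not called. No member of these lists passed over all genes or adjusted over the list alone.

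Camera called 6 of the 29 lists, 3 higher and 3 lower, and none of them with an estimated correlation, where the smallest adjusted p was 0.812, or with fry, where it was 0.889. The striatum list had the strongest call: it fell at an adjusted p of 2.65e-10 (adjusted p = 0.812 with an estimated correlation), with lower values for 12 of 12 genes and a median log2 fold change of -1.50. None of its genes passed over all genes and 8 passed adjusted over the list alone, with a smallest adjusted p of 0.0147. Drd2, the dopamine receptor of the indirect pathway, was at 8.26 ± 2.59 CPM against 29.8 ± 22.3, and Rgs9, a regulator of G-protein signalling, at 23.5 ± 4.24 against 81.7 ± 56.4 (SD, n = 3 each). Control library 3 held the highest value of every member and a list score of 1.77, against 0.31 and -0.088 in the other controls and between -0.75 and -0.60 in cell-treated libraries. Without it the median was -0.66. The list scores of the groups did not overlap, which gives an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries allow.

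The blood and leukocyte list rose at an adjusted p of 0.00027 by camera (adjusted p = 0.812 with an estimated correlation), with higher values for 7 of its 9 tested genes. The 5 that passed edgeR's test adjusted over the list alone, with none over all genes, were the hemoglobin chains Hba-a1, Hba-a2, Hbb-bs and Hbb-bt and the erythroid heme synthase Alas2. Their log2 fold changes were 2.96 ± 0.698, 3.58 ± 0.928, 2.68 ± 0.723, 2.46 ± 0.410 and 1.99 ± 0.555 (SE), and without control library 1 that of Hba-a2 was 5.52. The alpha and beta chains each have a near-identical copy, so single chains are uncertain. The lymphocyte genes Cd8a (-1.37) and Cd4 (-1.68) had lower values, and Ptprc, the common leukocyte antigen, had 0.052. The median of the list was 1.99, and it was 0.88 without cell-treated library 3 and 0.97 without control library 3.

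**Figure D2:**
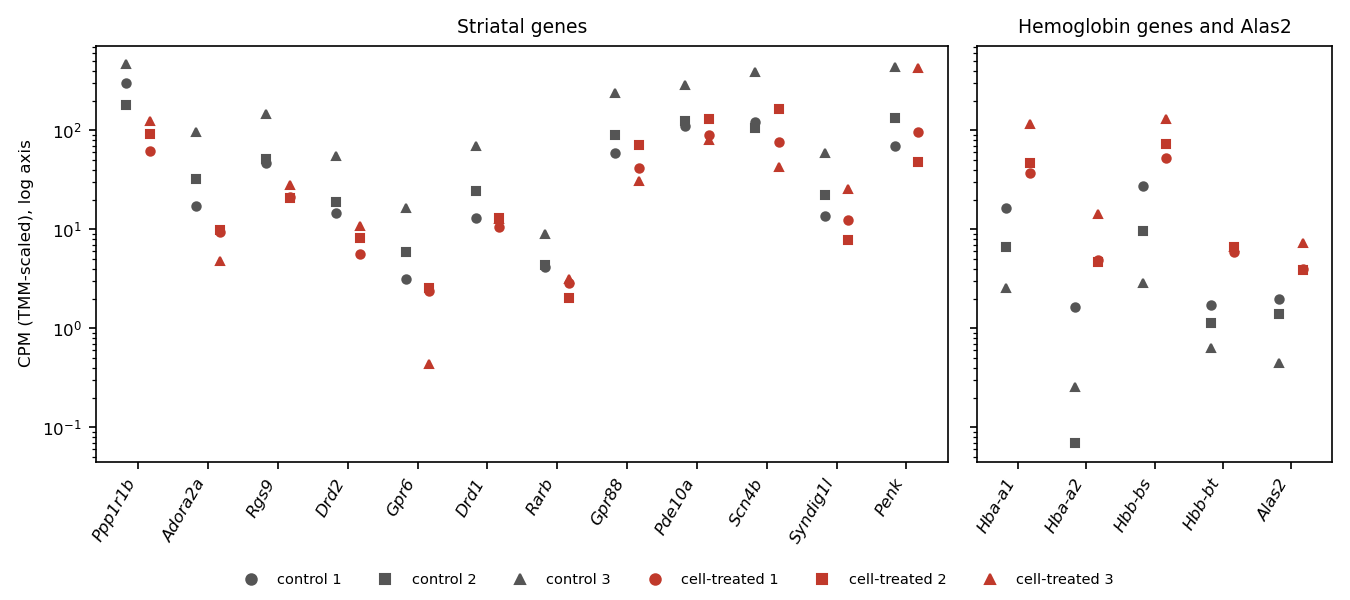
TMM-scaled CPM (log axis) of the 12 striatal genes and of the 4 hemoglobin genes with Alas2, 1 symbol per library. Adora2a lay between 4.79 and 9.93 CPM in cell-treated and between 17.1 and 96.0 CPM in control libraries, and Hbb-bs between 53.1 and 131 CPM in cell-treated and between 2.88 and 27.4 CPM in control libraries.

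The other 4 called lists moved with cell-treated library 3. Astrocyte genes fell at an adjusted p of 0.000587 (adjusted p = 0.812 with an estimated correlation), with lower values for 13 of 13 genes and a median of -0.51. Slc1a2, the main glutamate transporter, was at 699 CPM in that library and between 2670 and 4835 in the other 5. Without it the median was -0.11 and the adjusted p 0.465, and without control library 1 they were -0.33 and 0.0558. The median was -0.87 without cell-treated library 2. Oligodendrocyte and myelin genes fell at an adjusted p of 0.0273 (adjusted p = 0.812 with an estimated correlation), with lower values for 13 of 15 genes and a median of -0.24; Cnp, a myelin enzyme, was at 86.4 CPM in cell-treated library 3 and between 255 and 379 elsewhere. Without that library the median was 0.17 (adjusted p 0.209), without control library 1 -0.017 (adjusted p 0.377) and without cell-treated library 2 -0.77.

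Interferon response genes rose at an adjusted p of 0.00416 (adjusted p = 0.812 with an estimated correlation), with higher values for 21 of 22 genes. Irf7, an interferon regulatory factor, was at 34.6 CPM in cell-treated library 3 and between 2.82 and 5.38 in the other 5. Without that library the median was -0.20 instead of 0.51 (adjusted p 0.0529), without cell-treated library 1 it was 0.79, and without control library 3 the adjusted p was 0.0640. Reactive astrocyte genes rose at an adjusted p of 0.0229 (adjusted p = 0.812 with an estimated correlation), with higher values for 19 of 21 genes. Vim, an intermediate filament, was at 1015 CPM in cell-treated library 3 and between 89.1 and 290 elsewhere, whereas Gfap had a log2 fold change of -0.56 ± 0.387 (SE), which was -0.081 without control library 1. The median was 0.61, and it was -0.54 without cell-treated library 3 (adjusted p 0.209) and between 0.945 and 1.03 without control library 1 or 2 or cell-treated library 1 or 2; the adjusted p was 0.525 without control library 3. No gene of these 4 lists passed over all genes or adjusted over the list alone.

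**Figure D3:**
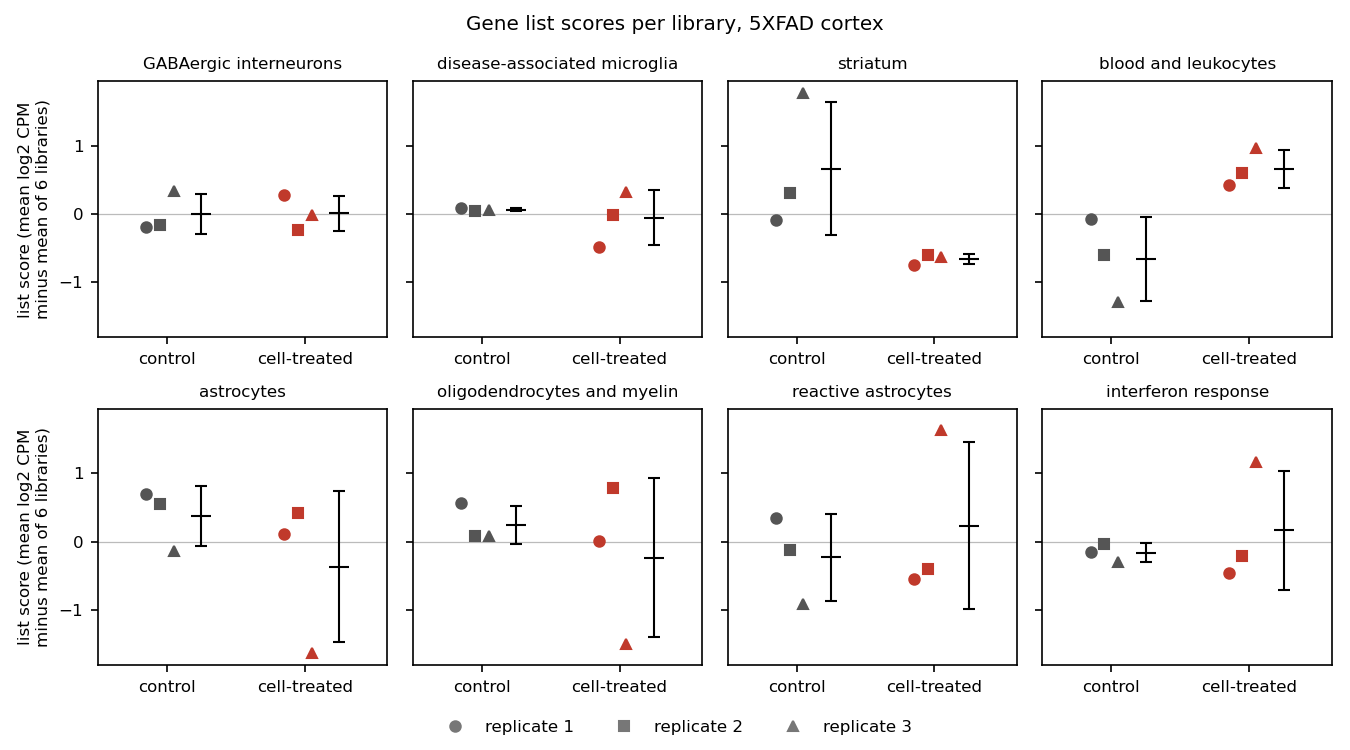
Scores of 8 gene lists in each library (mean over genes of log2 CPM minus the mean of the 6 libraries), with the group mean ± SD (n = 3). Cell-treated library 3 (triangle) lies at -1.64 for astrocytes and 1.64 for reactive astrocytes, and control library 3 (triangle) at 1.77 for striatum.

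The remaining lists were not called. Among neuronal lists, excitatory neurons (adjusted p 0.0774 by camera, median 0.20) and voltage-gated channels (0.0825, median 0.15) had higher values for 12 of 19 and 17 of 24 genes, with Neurod6 at 0.61 ± 0.280 (log2 fold change, SE), or 0.39 without cell-treated library 2. Both were called without cell-treated library 3, at 0.0188 and 0.00506, and without control library 3, at 0.0269 each. Those calls used camera's preset correlation. With an estimated one, run on all 6 libraries only, both lists had an adjusted p of 0.812. Without cell-treated library 2 their medians were 0.0655 and 0.079 (adjusted p 0.536 and 0.502), and without control library 2 they were 0.12 and 0.079 (0.352 and 0.411). Synaptic vesicle and scaffold genes had an adjusted p of 0.267, glutamate receptors 0.624 (0.0469 without cell-treated library 1, where the median was -0.25, against 0.13 without cell-treated library 3), activity-regulated genes 0.818 and neurotrophic factors and receptors 0.564. Among other cell types and regions, the adjusted p was 0.267 for oligodendrocyte precursors, 0.267 for endothelium and mural cells (0.00365 without control library 2, where the median was 0.38, against -0.030 without control library 3), 0.238 for fibroblasts and meninges, 0.678 for choroid plexus, 0.356 for hippocampus and 0.354 for thalamus and hypothalamus. Fibroblast and meningeal genes had a median of -0.49, and without control library 3 they had -0.81 at an adjusted p of 1.81e-06; the adjusted p was 0.0486 without cell-treated library 1. Without control library 2 the median was -0.0024 and the adjusted p 0.756. Autophagy and lysosome had an adjusted p of 0.238 (0.0148 without cell-treated library 1, where the median was 0.23, against -0.077 without cell-treated library 3), heat shock and stress 0.427 and mitochondrially encoded genes 0.427. Without control library 3 the mitochondrially encoded genes had a median of -0.51 and an adjusted p of 5.58e-05, and without control library 2 a median of 0.43 and an adjusted p of 0.000708. Every p-value here with a library left out used camera's preset correlation. With an estimated one, run on all 6 libraries only, no list had an adjusted p under 0.812. No member of these lists passed over all genes or adjusted over the list alone. The direction of the camera test differed in sign from the median and the mean for mitochondrially encoded, activity-regulated, neurotrophic and amyloid processing genes, from the median for complement and antigen presentation, and from the mean for disease-associated microglia.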

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

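Leaving out control library 3 and cell-treated library 3 together and limma voom with sample quality weights were chosen after seeing the data. The counts of 0 genes in each direction held under every alternative except DESeq2, which called 5 higher and 4 lower, all 9 with an absolute log2 fold change of at least 1, and edgeR without a low-count filter, which called 1 higher, also past that fold change. The cause was not tested. The smallest adjusted p ranged from 0.00013 (DESeq2) to 1, and it was 0.0838 with sample quality weights. The count of 6 called lists was 0 with an estimated correlation and 0 with fry, between 4 and 10 with single libraries left out, and 14 without control 3 and cell-treated 3. Of the 6 calls, 2 remained without cell-treated library 3 (striatum, blood) and 2 without both (striatum, astrocytes); the blood list then had an adjusted p of 0.0679.

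Medians of log2 fold changes reversed in sign with fewer samples for several lists. With single libraries left out, they ranged from -0.202 to 0.788 for interferon response, from -0.54 to 1.03 for reactive astrocytes, from -0.767 to 0.175 for oligodendrocytes and myelin, and from -0.505 to 0.43 for mitochondrially encoded genes. Without control 3 and cell-treated 3 the median was -0.253 for interferon response, -0.785 for reactive astrocytes and 0.141 for oligodendrocytes and myelin, against 0.505, 0.607 and -0.239 in all 6 libraries, and 0.265 for glutamate receptors against -0.0371. Interferon response and reactive astrocytes were then called as lower, at adjusted p-values of 0.00881 and 0.000245. For mitochondrially encoded genes (-0.585 against -0.0284) and activity-regulated genes (0.393 against 0.0523) the median kept its sign there, and the direction of the camera test reversed.

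The replicate numbers are not stated to pair the mice. Deviations of same-numbered libraries correlated at -0.277, 0.0815 and 0.0728, and control 1 correlated best with cell-treated 2 (0.16). With the replicate number as a block, 0 genes were higher, 0 lower and 7 lists called, and fibroblasts and meninges joined the 6. A sex term could not be fitted, since all libraries held Xist counts and 0 counts of 4 Y-linked genes.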

Other observations

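The gene lists in this part that are not among the fixed ones, and every test except the splits of the libraries for the gene lists, were chosen after the result was seen. Leaving out each library was planned for the fixed lists, and its use here to weigh an explanation was not. MHC class II genes, which present antigen to helper T cells, had lower values in cell-treated libraries for 6 of 7 genes, with a median log2 fold change of -1.22 and none past edgeR's test over all genes. Of the 7, 4 belong to the fixed complement and antigen presentation list, and their values had been seen: Cd74, H2-Aa, H2-Ab1 and H2-Eb1. Cd74 did not overlap between the groups, at 22.0, 38.3 and 30.1 CPM in cell-treated libraries 1, 2 and 3 against 42.8, 72.5 and 95.6 in controls, and H2-Eb1 had a log2 fold change of -1.29. Cd74 had been named by a rule that requires no overlap, so its separation is not support. The groups overlapped for each of the other genes of the 7. Among the genes not in that fixed list, H2-DMa had -0.25, H2-DMb1 0.11 and Ciita, the master regulator of the class, -0.30. Cd4, which T cells and some myeloid cells carry, had -1.68.

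Of 9 tested olfactory bulb genes, 8 were highest in cell-treated library 1, and Trh was highest in cell-treated library 3. The score of the list was 3.43 in cell-treated library 1, against -1.62, -0.54 and 0.20 in the controls and -1.62 and 0.16 in the other cell-treated libraries. Frmd7 was at 47.4 CPM in cell-treated library 1 and at most 1.85 elsewhere, Th at 44.5 and at most 8.83, and the interneuron genes Calb2 at 145 and at most 31.0 and Dlx1 at 110 and at most 32.0.

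The striatal genes were lower in cell-treated libraries. Of 19 further striatal genes, 16 had lower values, with a median of -0.88 that was -0.33 without control library 3. Control library 3 held the highest value of 16 of the 19, so they are not independent support. They include Rxrg, which was named above for its small p. Of the 12 fixed genes, 0 belong to another fixed list, although all 12 had counts in every library. Control library 3 was not the only source of the lower values. In the other 5 libraries the median was -0.664 (SE 0.248 over genes, which are not independent) and 11 of 12 genes were lower. The genes of the list move together (estimated correlation 0.632) and few controls remain. The values therefore cannot show that the remaining difference is beyond chance. Less striatal tissue in the cell-treated pieces cannot be told apart from an effect of the cell therapy on striatal neurons or on these genes in the cortex, which was not tested. The list score differed by 1.86 among the controls and by -1.33 between the groups, but the spread among the controls rests on control library 3. Without it, the controls differed by 0.395 and the groups by -0.773.

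The hemoglobin genes and Alas2 were higher in cell-treated libraries. Cell-treated library 3 was not the only source of the higher values. In the other 5 libraries the median of the 5 genes was 2.29, against 2.68 in all 6. Its SE of 0.247 is over genes, which are not independent. With few cell-treated libraries left, these values cannot show that the remaining difference is beyond chance. More red blood cells in the pieces may explain the pattern. The log2 ratio of Hba-a1 to Hbb-bs had an SD of 0.238 over the 6 libraries while log2 Hbb-bs had an SD of 2.04. The alpha and beta chains thus moved together. Any source that holds both transcripts would give this, so the ratio does not tell the explanations apart. Differences in perfusion or dissection and an effect of the therapy on blood vessels stay open and were not tested.

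Cell-treated library 3 stood apart from the other 5, with Igfbp3 at 109 CPM against at most 9.33. A shallower library is argued against by its total of 16696463 counts, above the 15607280 of the next. Of 10 genes of sensory ganglion or nerve tissue, 1 lay at least 2-fold above the next library and none was above 2.49 CPM in this library. Only 3 of the 10 passed the expression filter, and 2 of these 3 were highest in this library. Mrgprd and Pmp2 were listed at 0 in all 6 libraries. The low values argue against much tissue of that kind, and a small share of it stays open. Injured tissue in the piece may explain the pattern: of 17 tested genes known to rise around an injury, written down without looking at their values, 14 were highest in this library, and no other library held the highest value of more than 1. The most abundant were Fn1 at 309.5, Anxa2 at 62.5 and Flnc at 46.7 CPM. An effect of the therapy in this mouse alone stays open and was not tested.

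The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Genes past the adjusted threshold numbered 0 in the real split and 0 at most in the others, and with a real count of 0 the comparison says nothing. At an unadjusted p under 0.05 the real split gave 340 genes and the highest other 1549, and 9 of 10 splits gave as many as the real one. That highest split, with control 1, control 2 and cell-treated 2 on a side, gave several times the real count. It is the largest of the splits. The pairs among control 1, control 2 and cell-treated 2 correlated at 0.9775 to 0.9829 (Pearson, log2 CPM across genes). The other pairs correlated at 0.977 at most. The other side of that split holds control 3, cell-treated 1 and cell-treated 3, each described above for genes far higher there. The highest count thus went with a likeness of libraries that crosses the groups, and its cause was not tested. For gene lists the real split gave 6 and the highest other 17, and 9 of 10 splits gave as many as the real one.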
